A study of Mus musculus with 8 samples.

How the data were processed

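The data were RNA sequencing libraries of 8 mouse samples in 2 groups of 4, titled model and high dose. Per the labels' protocols, RNA was purified with an Rneasy kit and libraries were made with the SMARTER mRNA-Seq kit. The authors deposited 1 table of FPKM values (fragments scaled by feature length and library depth), with 1 column per library, 48632 rows and replicates not pooled. The header names no unit. FPKM was inferred from the values: decimals whose column sums, 845852 to 1249860, differed between libraries, and low values whose ratio between 2 libraries clustered at 1 value and at simple multiples of it, as whole fragments divided by a depth and a length would give. The genome build was mm39, per the submitters' processing notes. The aligner, the quantification tool and the annotation version were not given in the sources used here. Of the rows, 41617 had an entry in the gene name column, and 7015 had none there. Of the 7015, 704 had an identifier built from a gene symbol, 6065 that of a pseudogene, 117 that of a new gene and 129 another form, and these were not read as gene names. Coordinates were not used here, since the table gave none and the reference at hand was of another build.

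Relative depth was read from rows with FPKM below 0.3 in every library, as the most frequent ratio to model replicate 1. The tolerance was 0.015 on the log ratio, and about 5% of low rows lay within it in each library. This gave 1.00 to 1.34. Per library 245 to 293 low rows lay near that ratio and 215 to 273 near simple multiples of it, so these depths are approximate. Counts per gene were not recovered from it, so no count model was fitted, and the precision of each value rests on the spread between the 4 libraries of its group.

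Values were summed over rows with the same gene name, since 1734 names lay on more than 1 row (4061 rows). The 39290 names were filtered to a mean of at least 1 FPKM over the 8 libraries, which left 14418 genes. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with group as the only term and moderated variances with trend and robust settings, and p-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are high dose minus model on the log2(FPKM + 1) scale, which understates changes of genes with low values. SD is over the 4 libraries of a group on the FPKM scale and SE is that of the fitted log2 fold change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

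Gene lists, 24 of processes and 25 of cell type markers with 735 names of which 8 were absent from the gene name column (2 of them, Mx1 and Mx2, stood in identifiers only), were fixed before the data were examined, as were the design, the thresholds, the rule for named genes and the alternative settings other than those given as added. Summing over rows of 1 gene name was decided after the structure of the table was seen and before any test. The 44 lists with at least 5 tested members were tested together with limma's camera on the moderated statistics, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 44 lists. Camera with a correlation estimated per list and the rotation test fry were run as alternatives. A count adjusted over the list alone uses only the p-values of that list's members. A list of markers is not a count of cells.

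Genes were named by a rule. It took the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, groups that did not overlap and a mean of at least 1 FPKM in the higher group, leaving out predicted genes and immunoglobulin segments. It also took up to 4 members with the smallest p of each list that passed, and 10 genes of fibrosis, inflammation and oxidative stress whatever their result. Genes outside the rule are marked as named after their values were seen, or are given as list members or as markers of the tissue. Some genes that the rule took are not reported here.

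The fit was checked on simulated data in which 200 of 14418 genes were changed. At a log2 change of 0.5 the comparison recovered 21 of 67 changed genes (31.3%), at 1 it recovered 50 of 67 (74.6%) and at 2 it recovered 64 of 66 (97.0%), with 7 false calls among 142. The list test was checked on separate simulated data, in which only the list of collagens and matrix glycoproteins was shifted, by 1. That list was called, and 1 of the other lists was called too. Genes were drawn independently in both simulations, so the check does not bear on the preset correlation. In the data the estimated correlation was 0.49 for the matrix list and 0.80 for the type I interferon list.

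The alternatives were quantile normalization, median centring, no trend, no filter on low values, a minimum mean of 5 FPKM, pseudocounts of 0.1 and 0.01, an added fold threshold, the replicate number as a block, and each library left out in turn. Added after seeing the data were a fit on rows not summed per gene name and a fit on all rows. Alternatives meant for read counts did not apply. Rows without an entry in the gene name column were left out of the main test.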

Results

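RNA sequencing values were deposited for 8 mouse libraries, 4 titled as a model group and 4 titled as a high dose group. The title of the series names a mouse model of idiopathic pulmonary fibrosis, a scarring disease of the lung, and Platycodin D, a saponin from the root of Platycodon. How the model was made, the dose and an untreated group were not given in the sources used here. The labels name both lung tissue and MLF, a mouse lung fibroblast line, for each library. Transcripts of lung epithelium and vessels were abundant in both groups. Sftpc, a surfactant protein of alveolar type 2 cells, had a mean of 10199 ± 1944 FPKM in the model libraries and 13300 ± 2460 in the high dose libraries (SD, n = 4 each), and Pecam1, an endothelial adhesion molecule, had 219 ± 22.9 and 213.9 ± 21.2 FPKM. Below, model and high dose mean the libraries so titled. The library codes in the descriptions carry initials that would fit the opposite assignment, and every direction given here would turn if the titles were exchanged.

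The file held FPKM values and no read counts, so the number of reads per library was unknown. Ratios between libraries among rows of low FPKM placed the relative depth of the 4 model libraries at 1.00, 1.14, 1.17 and 1.03 and of the 4 high dose libraries at 1.22, 1.34, 1.21 and 1.08. Rows with an empty gene name entry, 7015 of 48632, took 50.0% to 65.2% of the FPKM sum of a library, and the single highest row took from 6.17% in model replicate 4 to 41.5% in high dose replicate 2. Spearman correlations between libraries, taken across genes, ranged from 0.895 to 0.975. The first principal component held 46.2% of the variance, with the model libraries between -49.2 and -4.02 and the high dose libraries between 21.8 and 34.6. Model replicate 4 lay apart from the other libraries on the second component, which held 18.0% of the variance, at -34.2 against -10.3 to 29.1. Nothing in the labels said whether the 4 libraries of a group came from separate animals, so p-values measured the spread between these libraries, which may be technical.

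The comparison of high dose with model asked which lung transcripts differed under the treatment in the fibrosis model. In the high dose libraries genes of the type I interferon response and neutrophil and natural killer cell transcripts were lower, and collagens and matrix glycoproteins, cholesterol synthesis enzymes and alveolar epithelial transcripts were higher. These are calls of gene lists with a preset correlation between genes, and none of them held with an estimated correlation (adjusted p = 0.356 to 0.427). Gbp4, a guanylate-binding GTPase of host defence, fell from 199 ± 80.5 to 15.2 ± 3.77 FPKM (SD, n = 4 each), a log2 fold change of -3.57 ± 0.29 (SE, adjusted p = 0.00144). Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 47.1 ± 11.3 to 327 ± 193 FPKM, a log2 fold change of 2.62 ± 0.39 (adjusted p = 0.00751). Of 14418 genes tested with limma, 845 were higher and 616 lower in high dose at an adjusted p under 0.05, and 3688 had an unadjusted p under 0.05. With a log2 fold change beyond 1 in either direction added to the threshold, 154 were higher and 266 lower. In 2559 genes (17.7%) the 4 and 4 libraries did not overlap, against 2.86% by chance, and the median log2 fold change of all tested genes was 0.04. Leaving out 1 model library gave, for genes higher and lower, 436 and 375 without model replicate 1, 1178 and 970 without model replicate 2, 364 and 329 without model replicate 3, and 509 and 412 without model replicate 4. Leaving out 1 high dose library gave 455 and 413 without high dose replicate 1, 559 and 411 without high dose replicate 2, 408 and 340 without high dose replicate 3, and 436 and 345 without high dose replicate 4.

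Leaving out immunoglobulin and predicted genes, the 10 largest rises among genes whose 4 and 4 libraries did not overlap were in Spp1, Jchain, Ccn1, Slc26a4, Mfap4, Mmp2, Areg, Tnc, Mmp12 and Eln, with log2 fold changes from 1.80 to 2.62. Ccn1, a matricellular protein, rose from 40.7 ± 9.66 to 241 ± 107 FPKM (log2 fold change 2.43 ± 0.38, adjusted p = 0.00862). Slc26a4, which encodes the anion exchanger pendrin, rose from 0.69 ± 0.186 to 6.87 ± 2.17 FPKM (2.19 ± 0.19, adjusted p = 0.00149, and 3.29 with a pseudocount of 0.01). Mfap4, a microfibril-associated glycoprotein, rose from 101.4 ± 56.0 to 429 ± 147 FPKM (2.13 ± 0.36, adjusted p = 0.0112). By the same rule the 10 largest falls were in Serpina3f, Gbp10, Gbp5, Ido1, Gbp4, Slfn4, Gbp2, Gzma, Igtp and Gbp6, with log2 fold changes from -3.71 to -3.10. Serpina3f, a serine protease inhibitor, fell from 52.3 ± 28.4 to 2.56 ± 0.58 FPKM (-3.71 ± 0.43, adjusted p = 0.00404). Ido1, which starts the breakdown of tryptophan, fell from 28.5 ± 27.1 to 0.739 ± 0.0229 FPKM (-3.58 ± 0.63, adjusted p = 0.0132). Igtp, an immunity-related GTPase, fell from 182 ± 61.1 to 19.1 ± 1.93 FPKM (-3.13 ± 0.23, adjusted p = 0.00108). The Gbp genes, Serpina3f and Igtp have close paralogs, and Slfn4 and Igtp were summed over 4 and 2 rows, so how reads were divided among the copies is uncertain. Tnc and Jchain missed the threshold in 5 of the 8 fits without 1 library: both without model replicates 1 and 3 and high dose replicate 1. Tnc was lost also without high dose replicates 3 and 4, and Jchain without model replicate 4 and high dose replicate 2. Their highest adjusted p, both without model replicate 3, were 0.0806 and 0.0900, and Jchain missed it also without the filter on low values (adjusted p = 0.0545).

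**Figure D1:**
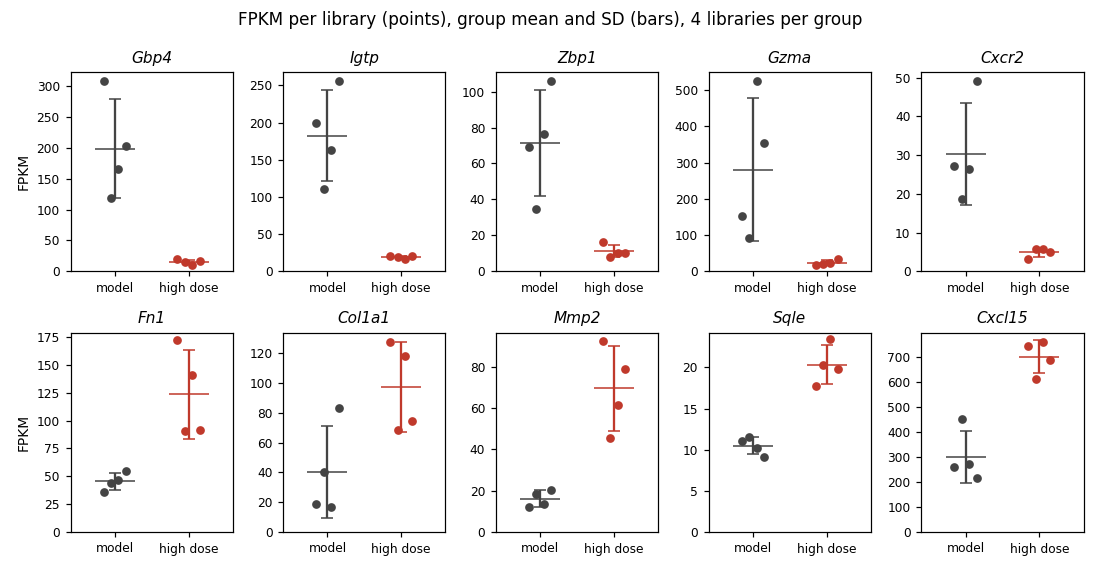
FPKM (linear axis from 0) of 10 genes in the 4 model libraries (grey) and the 4 high dose libraries (red), with each point 1 library and the bars the group mean and SD. The groups do not overlap in 9 of the 10 genes, and in Col1a1, which did not pass the test (adjusted p = 0.0923), they do.

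Gene lists fixed before the data were examined were tested with camera, and 44 of 49 lists had at least 5 tested members. With a preset correlation between genes, 14 lists were higher and 7 lower in high dose. With a correlation estimated for each list none passed: the smallest adjusted p was 0.356, and 3 lists had an unadjusted p under 0.05. By the rotation test fry, which does not compare a list with other genes, 13 lists were higher and 5 lower. Other splits of the 8 libraries into 4 and 4 gave up to 17 lists in 1 direction, so the number of lists alone does not exceed what regrouping gave. The rise or fall of single lists is therefore given with its member counts and with both adjusted p-values.

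Genes induced by type I interferon, an antiviral cytokine, were lower in high dose. Of 21 tested members 13 fell, 0 rose and 8 did not pass the test (21 fell adjusted over the list alone). Their median log2 fold change was -0.83 (adjusted p = 1.66e-19, and adjusted p = 0.356 with an estimated correlation). Zbp1, a sensor of nucleic acids, fell from 71.4 ± 29.3 to 11.2 ± 3.42 FPKM (SD, n = 4 each), a log2 fold change of -2.50 ± 0.33 (adjusted p = 0.00485). Oas3, an oligoadenylate synthetase, fell by 2.02 ± 0.30 on the log2 scale (adjusted p = 0.00668), and Cmpk2, a mitochondrial nucleotide kinase, by 0.72 ± 0.10 (adjusted p = 0.00459). Mx1 and Mx2, antiviral GTPases of the list whose rows had no gene name entry and were tested apart from the 21, had -0.24 ± 0.29 (adjusted p = 0.796) and -0.10 ± 0.18 (adjusted p = 0.881) and did not pass. Among the 8 that did not pass were Ifit1 (-0.52 ± 0.21, adjusted p = 0.167) and Ifit2 (-0.73 ± 0.23, adjusted p = 0.0828). The Gbp genes, Igtp and Ido1, among the largest falls, are not in this list. No list for other types of interferon was tested, so the fall is not assigned to 1 type. Inflammasome and cell death genes had 7 members lower, 0 higher and 13 not passing of 20 (9 lower adjusted over the list alone). Their median was -0.51 (adjusted p = 1.4e-07, and adjusted p = 0.356 with an estimated correlation). Among them Casp1, the protease that processes interleukin 1 beta, fell by 1.20 ± 0.22 (adjusted p = 0.0143), and Gsdmd, a pore-forming protein, by 0.92 ± 0.13 (adjusted p = 0.0049). Nlrp3, an inflammasome sensor, fell by 0.69 ± 0.12 (adjusted p = 0.0108), and Fas, a death receptor, by 0.60 ± 0.11 (adjusted p = 0.0139). Markers of 5 other leukocyte classes, 70 genes of T cells, B and plasma cells, both macrophage lists and dendritic cells, had a pooled median of 0.08.

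Transcripts that mark neutrophils and natural killer cells were lower in high dose. Of 13 neutrophil markers 10 fell, 1 rose and 2 did not pass (11 fell and 2 rose adjusted over the list alone). Their median was -2.11 (adjusted p = 8.62e-12, and adjusted p = 0.356 with an estimated correlation). Cxcr2, a chemokine receptor, fell from 30.3 ± 13.1 to 4.95 ± 1.16 FPKM (SD, n = 4 each; -2.33 ± 0.27, adjusted p = 0.00404). Csf3r, the receptor of granulocyte colony-stimulating factor, fell by 2.11 ± 0.29 (adjusted p = 0.00538). Mmp8, a collagenase stored in granules, fell by 2.42 ± 0.40 (adjusted p = 0.0101), and Stfa2l1, a stefin, by 2.47 ± 0.32 (adjusted p = 0.00458). The member that rose was Cd177, a surface glycoprotein named after its values were seen, with a log2 fold change of 1.64. Of 10 natural killer markers 9 fell, 0 rose and 1 did not pass (10 fell adjusted over the list alone). Their median was -1.86 (adjusted p = 7.58e-13, and adjusted p = 0.356 with an estimated correlation). Gzma and Gzmb, proteases of cytotoxic granules, fell from 281 ± 197 to 24.2 ± 6.69 FPKM (-3.21 ± 0.51, adjusted p = 0.0091) and from 30.8 ± 20.9 to 2.80 ± 0.604 FPKM (-2.81 ± 0.46, adjusted p = 0.00969). The receptor genes Klre1 and Klrb1c, which have close paralogs, fell by 1.86 ± 0.27 (adjusted p = 0.00623) and 1.63 ± 0.30 (adjusted p = 0.0139). T cell markers had 0 of 15 members passing in either direction, with a median of -0.05 (adjusted p = 0.102).

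Components of the phagocyte NADPH oxidase, which makes superoxide, were lower: 3 of 8 members fell, 0 rose and 5 did not pass (5 fell adjusted over the list alone). Their median was -0.76 (adjusted p = 0.00146, and adjusted p = 0.356 with an estimated correlation). Without the filter on low values, which adds members of low FPKM, it was -0.17 (adjusted p = 0.00112). Rac2 fell by 0.88 ± 0.20 (adjusted p = 0.0267) and Ncf4 by 1.02 ± 0.23 (adjusted p = 0.0267). Cybb, the catalytic subunit, had a log2 fold change of -0.96 ± 0.31 that did not pass (adjusted p = 0.0927, and 0.0146 without model replicate 2). Neutrophil markers fell in the same libraries, with a median of -2.11. Of 8 platelet markers 1 fell, 0 rose and 7 did not pass (6 fell adjusted over the list alone). Their median was -0.69 (adjusted p = 0.000811, and adjusted p = 0.403 with an estimated correlation). The member that fell was Ppbp, a platelet chemokine, from 53.3 ± 13.3 to 23.9 ± 11.2 FPKM (SD, n = 4 each; -1.17 ± 0.29, adjusted p = 0.0398). Gp9, Gp5 and Gp1ba, subunits of a platelet adhesion receptor, had log2 fold changes of -0.88 ± 0.30 (adjusted p = 0.102), -0.61 ± 0.21 (adjusted p = 0.103, and 0.0371 without high dose replicate 2) and -0.48 ± 0.16 (adjusted p = 0.0992, and -0.74 with a pseudocount of 0.01). The platelet list missed the threshold without model replicate 2 (median -0.59, adjusted p = 0.0535) and by fry (adjusted p = 0.101). Without 1 library the call of Rac2 was lost in 7 fits (each library but model replicate 2), with adjusted p up to 0.0746. The calls of Ncf4 (model replicates 1 and 3, high dose replicates 1 to 4) and Ppbp (model replicates 1, 2 and 4, high dose replicates 1, 3 and 4) were lost in 6 fits each, with adjusted p up to 0.107. Rac2, Ncf4 and Ppbp were lost without the filter on low values too (adjusted p up to 0.0763), and Ppbp also on rows not summed per gene name (adjusted p = 0.0580).

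Genes of the extracellular matrix were higher in high dose. Of 32 collagens and matrix glycoproteins 21 rose, 1 fell and 10 did not pass (27 rose and 1 fell adjusted over the list alone). Their median was 0.93 (adjusted p = 1.41e-17, and adjusted p = 0.356 with an estimated correlation). Fn1, which encodes fibronectin, rose from 45.2 ± 7.71 to 124 ± 40.0 FPKM (SD, n = 4 each; 1.39 ± 0.22, adjusted p = 0.00884), and Eln, which encodes elastin, from 49.1 ± 13.3 to 186 ± 97.3 FPKM (1.80 ± 0.33, adjusted p = 0.014). Bgn, a small proteoglycan, rose from 206 ± 22.6 to 419 ± 62.5 FPKM (1.01 ± 0.13, adjusted p = 0.00457). Col6a2 rose by 1.14 ± 0.17 (adjusted p = 0.00598), Col12a1 by 1.05 ± 0.12 (adjusted p = 0.00404) and Col18a1 by 0.89 ± 0.10 (adjusted p = 0.00311). The member that fell was Vcan, a large proteoglycan named after its values were seen, with a log2 fold change of -0.90. The main fibrillar collagens did not pass: Col1a1 had 39.9 ± 30.9 FPKM in model and 97.4 ± 30.2 in high dose (1.51 ± 0.49, adjusted p = 0.0923), and Col3a1 had 59.3 ± 50.1 and 150.2 ± 54.9 FPKM (1.59 ± 0.52, adjusted p = 0.0985). Without model replicate 4 both passed, with log2 fold changes of 1.95 (adjusted p = 0.0216) and 2.08 (adjusted p = 0.0204).

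Enzymes that crosslink and process matrix had 8 members higher, 1 lower and 9 not passing of 18 (8 and 1 adjusted over the list alone). Their median was 0.45 (adjusted p = 4.09e-05, and adjusted p = 0.356 with an estimated correlation). Loxl1, a lysyl oxidase that crosslinks elastin, rose from 14.3 ± 3.75 to 43.4 ± 2.88 FPKM (SD, n = 4 each; 1.57 ± 0.16, adjusted p = 0.00296). Adamts2, which trims procollagen, rose by 1.21 ± 0.17 (adjusted p = 0.00592). Pcolce, an enhancer of procollagen C-proteinases, rose by 0.95 ± 0.19 (adjusted p = 0.016) and the lysyl oxidase Loxl2 by 0.98 ± 0.20 (adjusted p = 0.0188). Of 16 matrix proteases and inhibitors 8 rose, 2 fell and 6 did not pass (11 and 4 adjusted over the list alone). Their median was 0.78 (adjusted p = 0.000758, and adjusted p = 0.356 with an estimated correlation). Mmp2, a gelatinase, rose from 16.1 ± 4.02 to 69.7 ± 20.5 FPKM (2.03 ± 0.24, adjusted p = 0.00404), and Mmp12, the macrophage elastase, from 1.98 ± 0.41 to 10.2 ± 4.46 FPKM (1.82 ± 0.28, adjusted p = 0.00791). Mmp11 rose by 0.92 ± 0.13 (adjusted p = 0.006) and Adamts1 by 0.70 ± 0.10 (adjusted p = 0.00633). The members that fell were Mmp8 and Mmp9, both also in the neutrophil list. Without 1 library Loxl2 missed the threshold in 4 fits (model replicates 1 and 3, high dose replicates 3 and 4; adjusted p up to 0.0568) and Pcolce in 1 (model replicate 1; adjusted p = 0.0507).

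Genes of TGF-beta signalling, the pathway of a growth factor that drives matrix production, had 6 members higher, 0 lower and 15 not passing of 21 (7 higher and 1 lower adjusted over the list alone). Their median was 0.30 (adjusted p = 0.000758, and adjusted p = 0.356 with an estimated correlation), and 0.16 without model replicate 4 or 0.19 without high dose replicate 3. Thbs1, a secreted glycoprotein that activates latent TGF-beta, rose from 41.3 ± 4.98 to 101.6 ± 26.4 FPKM (SD, n = 4 each; 1.25 ± 0.17, adjusted p = 0.00471). The ligand Tgfb3 rose by 0.77 ± 0.10 (adjusted p = 0.00458), and the latent TGF-beta binding proteins Ltbp3 and Ltbp2 by 0.71 ± 0.10 (adjusted p = 0.00514) and 1.29 ± 0.23 (adjusted p = 0.0138). The ligand Tgfb1 had 45.9 ± 4.97 FPKM in model and 46.5 ± 3.43 in high dose (0.02 ± 0.10, adjusted p = 0.92), with a sign that turned after median centring. Contractile genes of myofibroblasts did not pass as a list: 1 of 13 members rose and 12 did not pass, the same adjusted over the list alone, with a median of 0.19 (adjusted p = 0.613). Acta2, smooth muscle actin, had 89.3 ± 14.5 and 115 ± 31.7 FPKM (0.33 ± 0.22, adjusted p = 0.384, and 0.20 to 0.55 without 1 library).

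Markers of mesenchymal cells were higher too, with smaller medians than the matrix list. Of 15 fibroblast markers 4 rose, 0 fell and 11 did not pass (7 higher and 1 lower adjusted over the list alone). Their median was 0.51 (adjusted p = 0.0109, and adjusted p = 0.356 with an estimated correlation). Of the 15, 5 are also in the matrix list. Wnt2, a secreted signalling protein, rose by 0.90 ± 0.16 (adjusted p = 0.0131), and Mfap5, a microfibril protein, by 1.07 ± 0.24 (adjusted p = 0.0252). Dpt, dermatopontin, rose by 0.92 ± 0.22 (adjusted p = 0.0297) and Npnt, nephronectin, by 0.74 ± 0.17 (adjusted p = 0.0297). Of 13 smooth muscle and pericyte markers 3 rose, 0 fell and 10 did not pass (4 higher adjusted over the list alone). Their median was 0.25 (adjusted p = 0.0181, and adjusted p = 0.427 with an estimated correlation). Pdgfrb, a growth factor receptor, rose from 20.6 ± 3.81 to 33.8 ± 2.63 FPKM (SD, n = 4 each; 0.71 ± 0.13, adjusted p = 0.0139). The proteoglycan Cspg4 rose by 0.55 ± 0.13 (adjusted p = 0.0299) and the matrix protein Postn, which is also in the matrix list, by 0.47 ± 0.12 (adjusted p = 0.044). Hhip, a hedgehog-binding protein, had 0.66 ± 0.20 (adjusted p = 0.0758, and 0.0436 without model replicate 2). The fibroblast list missed the threshold without model replicate 1 (adjusted p = 0.0560) and the smooth muscle and pericyte list without model replicate 3 (adjusted p = 0.0520), and both at a mean of at least 5 FPKM (adjusted p = 0.0519 and 0.0568). Without 1 library Mfap5 was lost in 4 fits (model replicates 1 and 3, high dose replicates 1 and 4), and Dpt in 5 (those and high dose replicate 3), with adjusted p up to 0.0814. Npnt was lost in 6 (model replicates 1, 3 and 4, high dose replicates 1, 2 and 4), and Cspg4 and Postn in 6 each (model replicates 1 and 3, high dose replicates 1 to 4), with adjusted p up to 0.119. These 5 were lost also without the filter on low values (adjusted p up to 0.0837), Cspg4 after quantile normalization (0.0509) and Postn after median centring (0.0649).

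Alveolar and injured epithelial transcripts were higher in high dose. Of 10 markers of transitional or injured epithelium 7 rose, 0 fell and 3 did not pass (7 higher adjusted over the list alone). Their median was 0.86 (adjusted p = 8.25e-10, and adjusted p = 0.356 with an estimated correlation). Areg, a ligand of the epidermal growth factor receptor, rose from 3.41 ± 0.428 to 16.2 ± 3.34 FPKM (SD, n = 4 each; 1.95 ± 0.15, adjusted p = 0.00108), and Itgb6, an integrin subunit that activates TGF-beta, from 5.08 ± 1.52 to 13.7 ± 1.13 FPKM (1.31 ± 0.17, adjusted p = 0.00443). The tight junction gene Cldn4 rose by 1.47 ± 0.23 (adjusted p = 0.0079) and the keratin Krt7 by 0.81 ± 0.14 (adjusted p = 0.00964). Of 12 alveolar type 2 markers 7 rose, 0 fell and 5 did not pass (10 higher adjusted over the list alone). Their median was 0.55 (adjusted p = 4.49e-07, and adjusted p = 0.356 with an estimated correlation). Cxcl15, a lung chemokine, rose from 300.3 ± 106 to 702 ± 67.3 FPKM (1.28 ± 0.21, adjusted p = 0.00923). Abca3, a lipid transporter of lamellar bodies, rose by 0.56 ± 0.09 (adjusted p = 0.00936), the transcription factor Etv5 by 0.70 ± 0.12 (adjusted p = 0.0102) and the surfactant protein Sftpd by 0.74 ± 0.15 (adjusted p = 0.0181). Of 11 alveolar type 1 markers 5 rose, 0 fell and 6 did not pass (7 higher adjusted over the list alone). Their median was 0.51 (adjusted p = 0.00145, and adjusted p = 0.427 with an estimated correlation), and 0.34 without model replicate 4. Among them were Spock2, a proteoglycan (1.04 ± 0.19, adjusted p = 0.0127), and Aqp5, a water channel (0.82 ± 0.15, adjusted p = 0.0129). Cldn18, a tight junction protein (0.77 ± 0.17, adjusted p = 0.0244), and Pdpn, a membrane glycoprotein (0.51 ± 0.09, adjusted p = 0.00974), rose too. Without 1 library Cldn18 was lost in 4 fits (model replicate 3, high dose replicates 1, 2 and 4) and Sftpd in 2 (high dose replicates 3 and 4), with adjusted p up to 0.0730, and Cldn18 also without the filter on low values (0.0523).

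Enzymes and regulators of cholesterol synthesis were higher nearly throughout the pathway: 18 of 21 members rose, 0 fell and 3 did not pass (20 higher adjusted over the list alone). Their median was 0.56 (adjusted p = 5.68e-15, and adjusted p = 0.356 with an estimated correlation). Sqle, squalene epoxidase, rose from 10.5 ± 1.07 to 20.3 ± 2.40 FPKM (SD, n = 4 each; 0.89 ± 0.11, adjusted p = 0.00404). Cyp51, which removes a methyl group from lanosterol, rose by 0.78 ± 0.12 (adjusted p = 0.00721). Dhcr7, which catalyses the last step to cholesterol, rose by 0.64 ± 0.11 (adjusted p = 0.00975) and mevalonate kinase Mvk by 0.55 ± 0.09 (adjusted p = 0.0101). Genes of fatty acid synthesis and lipid storage did not pass as a list, with 3 of 17 members higher and 14 not passing, the same adjusted over the list alone. Their median of -0.01 and mean of 0.02 differed in sign, and the test was higher with an adjusted p of 0.059. The 3 that rose were the desaturases Scd1 (1.79) and Scd2 (0.59) and the elongase Elovl1 (1.39), named after their values were seen.

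Immunoglobulin transcripts were higher in high dose and varied between its libraries. Of 16 B and plasma cell markers 7 rose, 0 fell and 9 did not pass (8 higher adjusted over the list alone). Their median was 0.96 (adjusted p = 7.09e-06, and adjusted p = 0.356 with an estimated correlation), and 0.62 without high dose replicate 4. Igkc, the kappa light chain constant region, rose from 243 ± 92.4 to 1253 ± 1020 FPKM (SD, n = 4 each; 2.14 ± 0.48, adjusted p = 0.0278). The heavy chain constant genes Igha, Ighg2c and Ighg2b rose by 3.18 ± 0.65 (adjusted p = 0.0215), 3.12 ± 0.63 (adjusted p = 0.0198) and 2.90 ± 0.37 (adjusted p = 0.00458) on the log2 scale. Ighg2b and Ighg2c are near-identical in part and each lay on 3 rows, so their division of reads is uncertain. The B cell receptor gene Cd79b did not pass, with a log2 fold change of 0.74 (adjusted p = 0.176). Of 10 dendritic cell markers 2 rose, 0 fell and 8 did not pass (6 higher adjusted over the list alone). Their median was 0.48 (adjusted p = 0.0212, and adjusted p = 0.402 with an estimated correlation). These were the actin-bundling gene Fscn1 (0.90 ± 0.19, adjusted p = 0.0192) and the integrin Itgae (0.68 ± 0.15, adjusted p = 0.0255). Cd209a had 0.64 ± 0.21 (adjusted p = 0.0872, and 0.0188 without model replicate 2) and Batf3 0.33 ± 0.12 (adjusted p = 0.11). The dendritic list missed the threshold at a mean of at least 5 FPKM (adjusted p = 0.189) and without model replicate 4 (adjusted p = 0.0519). Without 1 library Igha and Igkc were lost in 4 fits each (model replicates 1, 3 and 4, high dose replicate 2), and Ighg2c in 2 (high dose replicates 1 and 3), with adjusted p up to 0.0843. Fscn1 was lost in 3 (high dose replicates 1, 3 and 4) and Itgae in 5 (model replicates 1, 3 and 4, high dose replicates 1 and 4), with adjusted p up to 0.0652. Without the filter on low values Igkc and Itgae were lost too (adjusted p = 0.0515 and 0.0522).

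Targets of the glucocorticoid receptor were lower as a list, with 4 of 12 members lower, 1 higher and 7 not passing (4 and 1 adjusted over the list alone). Their median was -0.41 (adjusted p = 0.0013, adjusted p = 0.474 with an estimated correlation and adjusted p = 0.135 by fry), and -0.66 without model replicate 1 or -0.17 without model replicate 4. Fkbp5, a chaperone partner of the receptor, fell from 70.8 ± 38.0 to 12.2 ± 2.80 FPKM (SD, n = 4 each; -2.28 ± 0.40, adjusted p = 0.0139). The transcription factor Zbtb16 fell from 60.3 ± 8.91 to 20.1 ± 2.63 FPKM (-1.54 ± 0.13, adjusted p = 0.00144) and Tsc22d3, a leucine zipper protein, from 201 ± 32.5 to 93.4 ± 19.8 FPKM (-1.11 ± 0.18, adjusted p = 0.00789). The member that rose was Lcn2, an iron-siderophore binding protein of neutrophils and epithelium, from 140.1 ± 29.2 to 363 ± 121 FPKM (1.33 ± 0.25, adjusted p = 0.0147). Targets of p53 and senescence genes had 7 of 15 members higher, 0 lower and 8 not passing (7 higher and 1 lower adjusted over the list alone). Their median was 0.39 (adjusted p = 0.00889, and adjusted p = 0.398 with an estimated correlation). Gdf15, a stress-induced cytokine, rose by 1.42 ± 0.26 (adjusted p = 0.0142), and Phlda3 by 1.14 ± 0.21 (adjusted p = 0.0141). Ccng1 rose by 1.02 ± 0.22 (adjusted p = 0.022) and the cell cycle inhibitor Cdkn2b by 0.89 ± 0.17 (adjusted p = 0.0143). Immediate early genes, transcribed within minutes of a stimulus, had 3 of 19 members higher, 0 lower and 16 not passing (7 higher and 2 lower adjusted over the list alone). Their median was 0.34 (adjusted p = 0.0495, and adjusted p = 0.761 with an estimated correlation). Egr1 rose by 1.83 ± 0.47 (adjusted p = 0.046), Egr2 by 1.35 ± 0.21 (adjusted p = 0.00715) and Ier3 by 0.80 ± 0.19 (adjusted p = 0.0301). Egr3 had 1.20 ± 0.34 (adjusted p = 0.0566, and 0.0346 without high dose replicate 4, 0.0482 with a pseudocount of 0.1 and 0.0479 with 0.01). The p53 list missed the threshold at a mean of at least 5 FPKM (adjusted p = 0.169) and without model replicate 2 (0.0682), and its median was 0.64 without model replicate 4. The immediate early list missed it at a mean of at least 5 FPKM (adjusted p = 0.343), by fry (0.266), without trend (0.0501) and without model replicates 1 and 2 and high dose replicates 2 and 3 (up to 0.549), and its median was 0.51 without high dose replicate 1. Ccng1 missed it without model replicates 1 and 3 and high dose replicate 3 (up to 0.0645). Egr1 and Ier3 missed it in 6 fits each (both without model replicates 1 and 4 and high dose replicates 2 to 4, Egr1 also without model replicate 2 and Ier3 without model replicate 3; up to 0.113). Both missed it without the filter on low values (up to 0.0802), and Egr1 after median centring (0.0520).

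Cytokine and chemokine genes did not pass as a list, with 5 higher, 2 lower and 20 not passing of 27 (7 and 4 adjusted over the list alone), a median of 0.23, a mean of -0.02 and an adjusted p of 0.785. Il1b, which encodes interleukin 1 beta, fell from 73.6 ± 15.6 to 25.0 ± 11.5 FPKM (SD, n = 4 each; -1.64 ± 0.37, adjusted p = 0.0292), a call lost without model replicates 1, 3 and 4 and high dose replicates 3 and 4 (adjusted p up to 0.0770) and without the filter on low values (0.0542). Tnf, tumour necrosis factor, had 2.70 ± 0.296 and 1.68 ± 0.95 FPKM (-0.52 ± 0.21, adjusted p = 0.158, and 0.0180 without high dose replicate 1; -0.81 with a pseudocount of 0.01). Il6, which encodes interleukin 6, lay below the expression filter and had 0.302 ± 0.121 FPKM in model and 1.46 ± 0.789 in high dose, with all high dose libraries above all model libraries (exact permutation test, two-sided, p = 0.0286, the smallest it can give with 4 against 4). The oxidative stress genes Hmox1, heme oxygenase, and Nfe2l2, the transcription factor NRF2, did not pass. Hmox1 had 36.1 ± 16.7 and 29.4 ± 4.70 FPKM (-0.19 ± 0.30, adjusted p = 0.745; -0.43 to 0.06 without 1 library), and Nfe2l2 had 74.7 ± 6.34 and 86.7 ± 6.79 FPKM (0.21 ± 0.09, adjusted p = 0.196). The list of antioxidant and NRF2 targets had 3 members higher, 1 lower and 23 not passing of 27 (4 and 1 adjusted over the list alone), with a median of 0.04 and a test in the lower direction (adjusted p = 0.984).

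**Figure D2:**
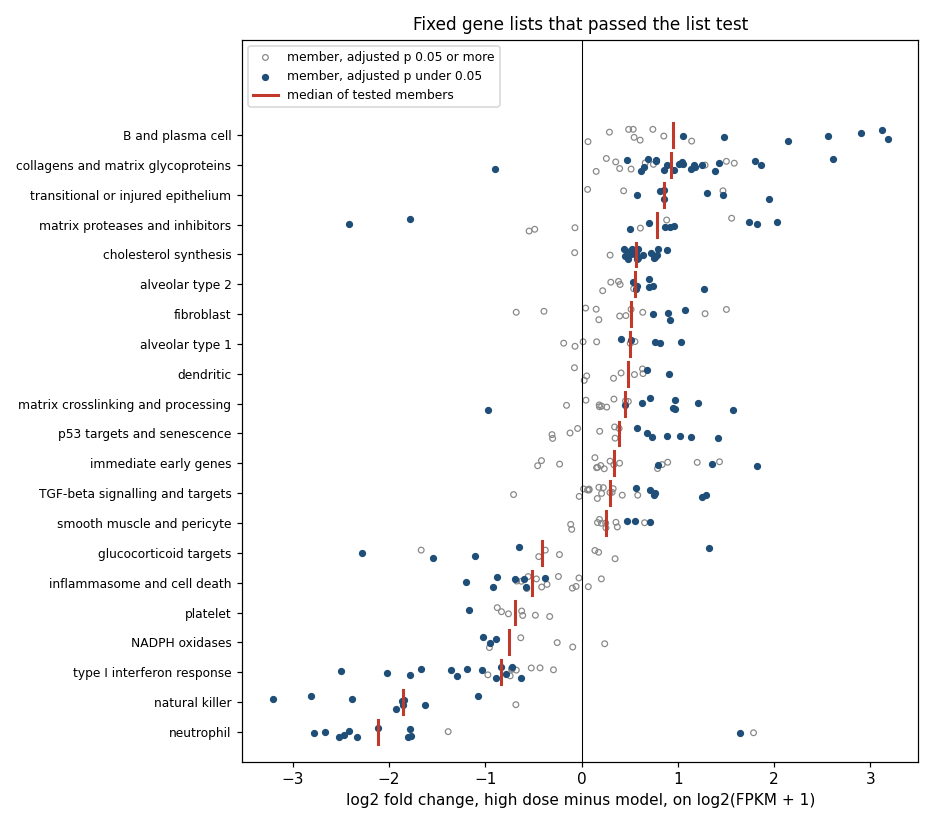
Log2 fold change, high dose minus model, of each tested member (points) of the 21 gene lists that passed the list test with a preset correlation, ordered by median (red bars), with filled points for members at an adjusted p under 0.05. The medians of the neutrophil and natural killer lists were -2.11 and -1.86, and those of the collagen and the B and plasma cell lists 0.93 and 0.96.

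The other process lists did not pass. The circadian clock list had 0 members higher, 4 lower and 13 not passing of 17 (adjusted p = 0.0583), and glycolysis and hypoxia 0, 2 and 19 of 21 (adjusted p = 0.0817). Higher, lower and not passing were 1, 0 and 9 of 10 for MHC class II antigen presentation (adjusted p = 0.182), 1, 1 and 16 of 18 for complement and acute phase (adjusted p = 0.749), and 2, 2 and 14 of 18 for NF-kB targets (adjusted p = 0.749). Adjusted over the list alone the counts higher and lower were 0 and 4, 0 and 2, 1 and 2, 1 and 1, and 4 and 5. No member passed in the lists of the cell cycle (0 of 26, median 0.04, adjusted p = 0.899), the unfolded protein response (0 of 17, 0.12, adjusted p = 0.524), nuclear genes of oxidative phosphorylation (0 of 25, -0.01, adjusted p = 0.613) and cytosolic heat shock (0 of 12, 0.09, adjusted p = 0.706), nor adjusted over the list alone. The median and the test differed in sign for complement and acute phase genes, with a median of 0.05, a mean of -0.08 and a test in the lower direction.

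Among markers of other cell types, no member passed for endothelial (0 of 14, median 0.06, adjusted p = 0.626), ciliated (0 of 13, 0.14, adjusted p = 0.613) and club and secretory markers (0 of 9, -0.38, mean 0.06, adjusted p = 0.749). None passed for erythroid (0 of 8, 0.47, adjusted p = 0.749), adipocyte (0 of 9, -0.96, adjusted p = 0.102) and cardiac and skeletal muscle markers (0 of 12, -0.34, adjusted p = 0.305), and the counts were the same adjusted over the list alone. Of 12 alveolar macrophage markers 1 rose, 2 fell and 9 did not pass (2 and 2 adjusted over the list alone; median -0.02, adjusted p = 0.626). Of 17 monocyte and interstitial macrophage markers 1 rose, 1 fell and 15 did not pass, the same adjusted over the list alone, with a median of 0.01, a mean of -0.03 and a test in the lower direction (adjusted p = 0.457). The 2 that passed were Spp1, which rose, and Ly6c2, a monocyte surface protein named after its values were seen, with a log2 fold change of -1.90. Of 6 mesothelial markers 1 rose, Krt19, and 5 did not pass, the same adjusted over the list alone (median 0.08, adjusted p = 0.891). Basal and lymphatic endothelial markers with 4 tested members each, mast cell and basophil markers and lymphoid follicle genes with 3 each, and hepatocyte markers with 0 were too few to test.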

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

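All explanations below were tested after the result was seen, except the tests of fibroblast share, transcript length and regrouping of libraries, whose outcomes were predicted first.

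Single libraries lay apart from the other 3 of their group in 9 of 220 groups of values examined, where chance at 1 in 20 gives 11. They were Slc26a4 in model replicate 4 (0.415 FPKM, others 0.758 to 0.826), Mfap4 in model replicate 2 (185 FPKM, others 67.2 to 79.0), Col12a1 in high dose replicate 2 (4.76 FPKM, others 6.21 to 6.55), Mvk in high dose replicate 3 (13.1 FPKM, others 10.5 to 10.9), Ppbp in model replicate 3 (33.6 FPKM, others 56.7 to 62.9) and in high dose replicate 2 (40.7 FPKM, others 17.3 to 19.0), Fscn1 in model replicate 1 (5.86 FPKM, others 9.60 to 9.86), Egr3 in model replicate 3 (1.14 FPKM, others 2.14 to 2.23) and Tnf in high dose replicate 1 (3.10 FPKM, others 1.06 to 1.31). These values were spread over 7 of the 8 libraries.

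Rows with an empty gene name entry, which the test of named genes left out, also differed between groups. Of 766 tested, 5 were higher and 28 lower in high dose. Of the 5, 4 carried identifiers of pseudogenes and 1 that of a new gene in the authors' table. Of the 28, 15 had identifiers built from a gene symbol, among them H2-K2, H2-Q5, Gbp11 and Oas1b, 7 those of pseudogenes and 6 those of new genes, the most abundant of which fell from 44287 ± 9871 to 17307 ± 2585 FPKM (SD, n = 4 each).

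The 845 genes higher and 616 lower were each larger than in any of the other 34 splits of the 8 libraries into 4 and 4, where the highest count in either direction was 1. The real split was the only 1 of 35 with a count as large (p = 0.0286, the smallest this exact test can give). A chance division of the libraries was thus argued against for both, but not excluded. For gene lists it was not argued against. Since a split has no direction of its own, the larger of both was counted. At least 14 lists in 1 direction were given by 12 of 35 splits and at least 7 by 32 of 35, and the highest other count was 17. In a test added afterwards on each list alone, 19 of 44 lists had a larger mean statistic at the real split than at any other (p = 0.0286, the smallest this exact test can give, adjusted p = 0.0662). These were 18 of the 21 lists that passed, leaving out NADPH oxidases (2 of 35 splits as large), platelet (2 of 35) and immediate early genes (5 of 35), and the circadian clock list.

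Type I interferon response genes were lower in high dose. Fewer leukocytes of every type would lower all leukocyte markers, and the pooled median log2 fold change of 70 markers of 5 leukocyte classes was 0.0829, with a first quartile of -0.137, above the third quartile of the interferon list at -0.721. Library scaling would shift all genes alike. It was argued against by the median log2 fold change of all tested genes, 0.04, beside the list median of -0.83. Centring each library on its median gene shifts all genes equally and could move the list little, so it adds no separate evidence. The list median was then -0.86 (camera with the preset correlation, adjusted p = 2.25e-20, against 1.66e-19 before centring). With an estimated correlation the list before centring had an adjusted p of 0.356. A lower interferon signal under the treatment may remain, as a hypothesis, and an exchange of the group titles, which would turn the direction, stays open. Fewer neutrophils and natural killer cells alone, which fell too, were not separated from it.

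Matrix genes were higher in the libraries titled high dose, with a list median of 0.93. A larger share of all fibroblasts would raise fibroblast markers by as much, and those chosen beforehand as not being matrix components were examined. Their median was 0.180 with an SD of 0.576, below the first quartile of the matrix list at 0.646 and more than 1 SD below its median. These markers went both ways. Wnt2 (0.90) and Npnt (0.74) rose, while Tcf21 (0.46), Fgf10 (0.18), Pdgfra (0.04), Thy1 (-0.39) and Pi16 (-0.68) did not pass. Left out of the choice were Dpt (0.92), Mfap5 (1.07) and Col13a1 (0.64, which did not pass), fibroblast markers that are not in the matrix list either. The median thus depends on which markers were chosen. It cannot decide on a larger share of all fibroblasts or of 1 kind of fibroblast. Transcript length bias was argued against by 10000 random lists matched on expression and length, whose highest median was 0.25. An exchange of the group titles cannot be told apart from a rise under the treatment: 31 of 32 members had a positive log2 fold change, which such an exchange would make negative, and no untreated library was analysed here to place the groups. More matrix transcription under the treatment therefore stays a hypothesis.

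Neutrophil and natural killer markers, and platelet markers by less, were lower in high dose. Less blood in the tissue would lower erythroid transcripts as well, whose list mean differed by 0.29 (high dose minus model), or by -0.086 without high dose replicate 2, so its direction rests on that library; the lowest high dose library lay -0.81 from the highest model library, which does not reach the natural killer median of -1.86 or the lower neutrophil median but spans the platelet median of -0.69, so for platelets this cannot be told apart. No single library carried these falls: over the fits without 1 library the list median nearest 0 was -1.64 for neutrophils and natural killer cells and -0.593 for platelets, with the third quartile of the members at most at -1.39 and -0.473. The platelet call ended without model replicate 2 (adjusted p = 0.0535), where the SD of the statistics of all genes was 2.87 against 2.27 with all libraries, and the list's mean statistic of -2.17 was close to the -2.19 without high dose replicate 1, where the call held. Fewer of these cells under the treatment, a lower content of these transcripts per cell, and exchanged titles stay open, and for platelets less blood does too. Less blood as a part of the neutrophil and natural killer falls was not excluded, since the erythroid list varied between libraries.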

How the results depend on the processing

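Fits on rows not summed per gene name and on all rows were chosen after seeing the data. Of genes higher and lower (845 and 616), fewer passed without the low-value filter, which tested 29739 genes (518 and 438), and with a log2 fold change over 1 added to the threshold (154 and 266). Leaving out 1 library gave 364 to 1178 higher and 329 to 970 lower, mostly fewer with fewer libraries; why more passed without model replicate 2 was not tested. Apart from the replicate number as a block, the other settings gave 674 to 861 higher and 488 to 692 lower, and quantile normalization shared 1349 of the 1461 called genes. With an estimated correlation 0 lists were higher and 0 lower, against 14 and 7; other settings gave 10 to 16 higher and 5 to 8 lower, and fits without 1 library 12 to 15 higher and 7 to 10 lower.

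Reversed in sign were Tgfb1 (median centring -0.0029, without model replicate 1 -0.024, without model replicate 2 -0.018, without high dose replicate 3 -0.015, fits without 1 library up to 0.078) and Hmox1 (without model replicate 4 0.065, lowest -0.43 without model replicate 1), both not past the threshold in any of these, and the cause was not tested. Other fold changes of named genes kept their direction: over all pairs of gene and setting, apart from fits without 1 library, 1037 kept their side of the threshold, 34 lost it and 2 gained it. Without 1 library 753 kept it, 107 lost it and 8 gained it, and 70 of 94 called genes and 15 of 21 passing lists kept their call in all 8 fits.

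With the replicate number as a block (replicate block), 486 genes were higher and 469 lower, 889 of them among the 1461, and 13 lists were higher and 8 lower. Calls lost under it were those of 14 named genes and 1 list, the dendritic one (adjusted p = 0.0527). Among the genes were Eln (adjusted p = 0.0506), Phlda3 (0.0518), Gdf15 (0.0551), Sftpd (0.0582), Tnc (0.0609) and Il1b (0.0701). Whether the numbers pair the samples was not settled. Correlations of the deviations of libraries with the same number were 0.154, 0.276, -0.068 and -0.092. Numbers 1 and 2 correlated best with their own, and the others did not. Planned settings for read counts were not run, since the table held FPKM. Depth in reads was unknown, and the simulated data showed 31.3% of genes recovered at a log2 change of 0.5.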

Other observations

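The tests of gene families were chosen after the data were seen, and the circadian clock list was fixed before. Grouping tested genes by the stem of their symbol gave 459 families, of which 21 had an adjusted p under 0.05 with camera at the preset correlation and 0 with an estimated correlation (adjusted p = 0.992 for each). All 10 tested guanylate-binding protein genes (Gbp) fell, with a median log2 fold change of -2.96 (adjusted p = 4.34e-32), as did all 7 tested Ly49 receptor genes (Klra), with a median of -1.85 (adjusted p = 1.72e-10). Of 15 Ifi genes 9 fell (median -0.93), of 7 Slfn genes 5 fell (-0.92), and of 10 genes with the stem Ms 5 fell, all of the Ms4a membrane proteins (-1.11). The stem H joins histone and histocompatibility genes: of 53 tested 12 fell and 1 rose. The 12 were all class I histocompatibility genes, which present peptides to T cells, among them H2-K1 (-0.79 ± 0.13, SE), H2-D1 (-0.67 ± 0.14), H2-T23 (-1.66 ± 0.18) and H2-Q4 (-1.29 ± 0.14), and the 1 was H2-DMb2 of class II (0.61 ± 0.16). For 18 of the 21 families the real split of the libraries gave a larger mean statistic than any of the other 34 splits. The others were Ifit and Oas (2 of 35 splits as large, the real one included) and Mir (3 of 35). The 21 families were picked by their statistic at the real split, so this adds no independent evidence. Each family median kept its sign after quantile normalization and after median centring, which shifts all genes equally and could change little. Gbp, Klra, Slfn and class I histocompatibility genes have close paralogs, so the division of reads among them is uncertain.

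Variable segments of immunoglobulin genes were higher: 23 of 73 Igkv and 20 of 65 Ighv segments rose, with medians of 1.68 and 1.42 (adjusted p = 2.42e-15 and 5.81e-12), and 1 Ighv segment fell. Of 10 Wnt ligand genes 5 rose, Wnt5a (0.92 ± 0.14, SE), Wnt7b (0.90 ± 0.15), Wnt2 (0.90 ± 0.16), Wnt7a (0.87 ± 0.16) and Wnt3a (0.70 ± 0.15), with a family median of 0.64 (adjusted p = 6.26e-05), and of 7 Fzd genes, their receptors, 2 rose (median 0.24, adjusted p = 0.0484). Of 13 Klf transcription factor genes 5 fell, Klf13 (-0.76 ± 0.12), Klf9 (-0.54 ± 0.10), Klf15 (-1.21 ± 0.25), Klf3 (-0.37 ± 0.08) and Klf10 (-0.58 ± 0.15), with a median of -0.37 (adjusted p = 0.000307). In the circadian clock list the 4 members that fell were the repressor genes Per2 (-0.77), Cry1 (-0.68), Per1 (-0.64) and Cry2 (-0.41). Per1 is also among the glucocorticoid targets that fell, so these lists are not separate. The time of day of sampling was not given in the sources used here.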
